A study of Homo sapiens with 28 samples.

How the data were processed

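Gene counts from RNA sequencing were examined for 28 libraries made from 8 primary acute myeloid leukemia (AML) specimens. Per the labels' protocols, thawed cells were sorted by flow cytometry into the 10% with the highest and the 10% with the lowest surface CD99, either from bulk blasts (low CD45 and low side scatter) or from the LMPP/MLP fraction (CD34-positive, CD38-negative, CD45RA-positive, CD90-negative), which the submitters describe as enriched in leukemic stem cells. RNA was extracted with Trizol LS and libraries were made with SMARTer amplification, per the labels' protocols.

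The deposited files hold whole-number read counts per Ensembl gene identifier, 57773 in each file, with 5 further summary rows that name no gene. Per the submitters' processing notes, HTSeq and Picard were used. The aligner, the genome build, the annotation release, the strand setting and the tool versions are not given in the sources used here. No coordinates are printed for that reason. Symbols were taken from a GENCODE v29 annotation and a table of gene names, matched on the identifier for 52338 identifiers (90.6%).

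The summary rows were left out of library sizes and tests. They held between 47.5% and 56.0% of all counts in a bulk file and between 43.3% and 55.0% in the other files. The deposited counts were not made alike in the 2 fractions. Each bulk file lists 7.51 to 19.75 M reads (M for mega) under the quality limit, 3.37 to 9.14 M unaligned reads and 0 reads without a unique alignment. Each LMPP/MLP file, and both files of specimen 8, list 0 of the first pair of classes and 7.44 to 13.59 M reads without a unique alignment. Reads that fit a gene and its copies may therefore have been handled differently in the 2 fractions, and these rows do not tell how. Reads of a gene and an overlapping or antisense neighbour cannot be told apart where strand was not used.

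Reads assigned to genes ranged from 22.5 to 67.6 M per library. SMARTer reads carry no molecular identifiers here, so the precision this depth gives covers counting error only. No pair of the 28 libraries agreed within sampling noise: the smallest chi-square per degree of freedom among the 378 pairs was 20.6. XIST, TSIX and Y-linked genes outside the shared regions, 474 identifiers, were kept in library totals and left out of every test and table.

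Specimens 1 to 6 had both fractions, specimen 7 had LMPP/MLP libraries, and the 2 libraries of specimen 8 carried conflicting fraction labels, so that they entered only the comparison that needs no fraction. The submitters' design text states that both CD99 populations came from each specimen, so the specimen number was used as a block in each fit. Libraries of the same number deviated together from their group means: the correlation across genes between the high and low library of a specimen was 0.471 to 0.688 in bulk and 0.445 to 0.797 in LMPP/MLP, and each library correlated best with its own number in 6 of 6 and 7 of 7 pairs. Bulk and LMPP/MLP libraries of the same number correlated at 0.304 to 0.698 for CD99 high and 0.263 to 0.665 for CD99 low, best with their own number in 6 of 6.

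Tests used edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with its default minimum of 10 reads, robust quasi-likelihood fits and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. The 5 comparisons were CD99 high against low in bulk, the same in LMPP/MLP, the same over 8 specimens with each specimen's counts summed per CD99 level, the difference of the CD99 effect between fractions (13 blocks and an interaction term), and LMPP/MLP against bulk with counts summed per specimen and fraction. Fixed gene lists, 37 in all, were tested with camera (limma 3.58.1) wherever at least 5 members were measured, with adjustment over the lists. The inter-gene correlation was preset at 0.01, and the test was repeated with an estimated correlation. Estimates ran from -0.07 to 0.87 over the lists in bulk and from -0.04 to 0.93 in LMPP/MLP. Where an estimate lies well above 0.01, p at the preset correlation overstates the evidence. Single genes and list medians were tested within specimens by two-sided exact permutation, flipping high and low in every combination, with adjustment over the 4 gate genes tested in every comparison (THY1 passed the filter for the difference between fractions alone) or over the lists of a comparison. CPM values are TMM-normalized.

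Genes are named by a rule set before the data were examined, as were the lists, the designs and all other settings below except those said to be added. CD99, CD34, CD38, PTPRC and THY1 are named throughout where measured. The 10 genes with the largest fold change in each direction are named among those past the threshold with an average log2 CPM of at least 2 and the same sign in all pairs or all but 1, skipping clone names. Where none passed, the 5 with the smallest p in each direction are given as values, under the same conditions on level and sign. Up to 4 members with the smallest p are named for a list that is described. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

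The same functions were tested on simulated counts with 200 changed genes. These counts were drawn once per comparison, each gene on its own, from edgeR's fitted means and dispersions. That setting may favour edgeR over the other tools. For the bulk comparison (21054 genes) edgeR recovered 1.49% of genes changed 1.5-fold, 8.96% of those changed 2-fold and 54.5% of those changed 4-fold, with 1 false call among 44. For LMPP/MLP (17838 genes) the shares were 16.4%, 41.8% and 81.8%, and for 8 specimens (23002 genes) 5.97%, 40.3% and 84.8%. For the difference between fractions (23305 genes) they were 0%, 2.99% and 36.4%, and for LMPP/MLP against bulk (23160 genes) 0%, 8.96% and 62.1%. In the same simulated bulk counts DESeq2 made 160 calls, of which 67 were false, and limma voom made 50, of which 2 were false.

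The alternatives were median-of-ratios size factors, no filter on low counts, a stricter filter (CPM of at least 5 in at least 0.5 of the libraries), DESeq2 1.42.0, limma voom with sample weights, a fit without the specimen block, leaving out each specimen, adding specimen 8 to either fraction, the number of genes detected as a covariate, unsummed fits and an estimated correlation for the lists. Restrictions to protein-coding genes or to genes without a named pseudogene, and thinning all libraries to one depth before summing, were added after the data were seen, as were 1000 random pairings of parent genes with pseudogene medians, dealt over all families.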

Results

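Transcript levels were measured by RNA sequencing in AML blasts sorted for high or low surface CD99, a transmembrane glycoprotein of leukocytes. The design compares both populations within each of 8 specimens. There were 6 CD99 high and 6 CD99 low libraries of bulk blasts, 7 and 7 of the LMPP/MLP fraction, and 1 and 1 of specimen 8, whose fraction labels conflict. Reads assigned to genes, in M (mega), averaged 34.4 M ± 5.05 (SD, n = 6) in bulk CD99 high, 44.6 M ± 13.2 (n = 6) in bulk CD99 low, 31.9 M ± 4.81 (n = 7) in LMPP/MLP CD99 high and 29.7 M ± 5.18 (n = 7) in LMPP/MLP CD99 low libraries. They were 37.9 M and 27.8 M in the CD99 high and CD99 low libraries of specimen 8.

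The sort was visible in the CD99 transcript (ENSG00000002586) in every specimen. In bulk blasts CD99 was higher in the CD99 high population in 6 of 6 specimens, by a mean log2 difference of 1.77 ± 0.78 (SD, n = 6; two-sided exact permutation p = 0.03125, the smallest 6 pairs can give, and 0.0625 adjusted over 4 gate genes). In LMPP/MLP cells it was higher in 7 of 7, by 0.80 ± 0.47 (SD, n = 7; exact permutation p = 0.0156, the smallest 7 pairs can give, and 0.0625 adjusted over 4 gate genes). Among all genes, CD99 did not pass edgeR's quasi-likelihood test in either fraction alone (log2 fold change 1.77, SE 0.29, adjusted p = 0.115 in bulk; 0.79, SE 0.15, adjusted p = 0.961 in LMPP/MLP). It passed over 8 specimens (1.25, SE 0.17, adjusted p = 0.0236, higher in 8 of 8). That call ended without specimen 1, 3, 6 or 8 (log2 fold change 1.19 to 1.29, adjusted p = 0.0765, 0.0646, 0.0510 and 0.0719) and with no specimen block (1.02, adjusted p = 1), and over all alternatives the adjusted p ran from 6.12e-08 with DESeq2 to 1. The difference was larger in bulk than in LMPP/MLP in 5 of the 6 specimens with both fractions, by 0.92 ± 0.65 (SD, n = 6; exact permutation p = 0.0625, and 0.125 adjusted over 4 gate genes). DESeq2 called CD99 in both fractions, with adjusted p = 9.75e-07 and 0.0046.

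**Figure D1:**
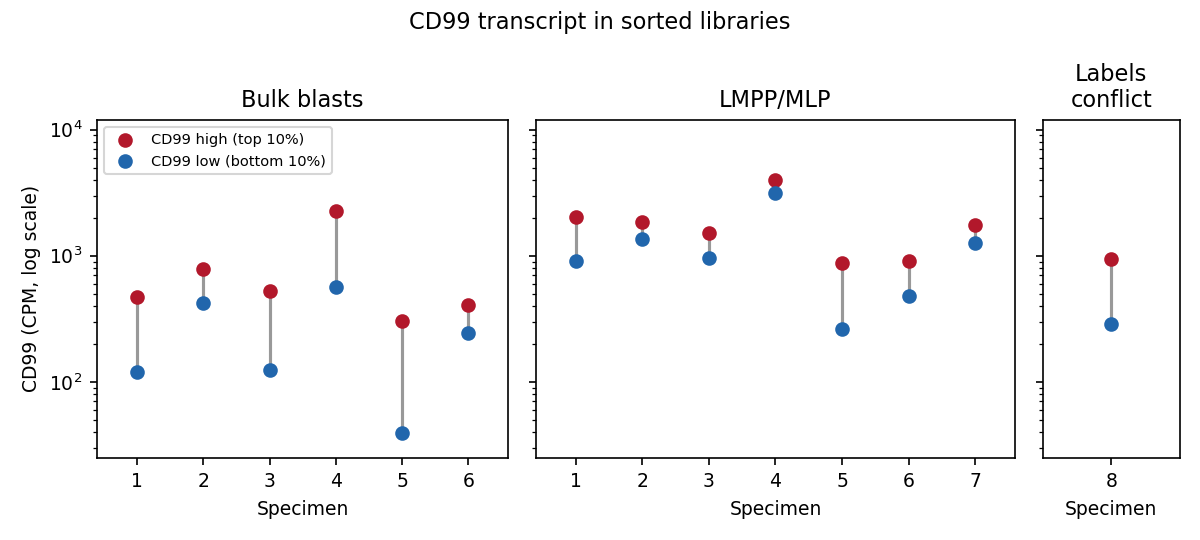
CD99 CPM (log scale) in each library, by specimen, for bulk blasts, LMPP/MLP cells and the specimen with conflicting labels; grey lines join the CD99 high and CD99 low library of a specimen. The CD99 high library lies above the CD99 low library in 6 of 6, 7 of 7 and 1 of 1 specimens.

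In bulk blasts the genes with the smallest p that were higher in CD99 high cells included STAB1, a scavenger receptor (log2 fold change 2.02, SE 0.22), CSF2RA, the GM-CSF receptor alpha chain (1.12, SE 0.13), GLIPR1 (1.98, SE 0.24), LY86, which binds the TLR4 relative RP105 (1.89, SE 0.25), and DOCK1, an activator of RAC (1.52, SE 0.20). Those lower in CD99 high cells were LTBP1, a TGF-beta binding protein (-4.17, SE 0.35), TNIK (-2.59, SE 0.31), C2orf88 (-2.26, SE 0.27), the zinc transporter SLC39A3 (-0.80, SE 0.10) and CD226, an activating receptor of lymphocytes and platelets (-4.01, SE 0.50). All 10 moved one way in 6 of 6 specimens, and none passed the test: edgeR's adjusted p lay between 0.0672 and 0.0890. CD34 had a log2 fold change of 2.48 (SE 0.76, higher in 6 of 6, adjusted p = 0.36), PTPRC, which encodes CD45, of 0.55 (SE 0.16, higher in 5 of 6, adjusted p = 0.338) and CD38 of -1.07 (SE 0.57, higher in 2 of 6, adjusted p = 0.674). THY1, which encodes CD90, was below the filter. No gene of 21054 was called by edgeR, with 1871 at an unadjusted p under 0.05. DESeq2 called 751, limma voom 52, and edgeR 164 without a filter and 56 with specimen 8 added.

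Antigen presentation genes stood higher in CD99 high bulk blasts. All 11 MHC class II genes had positive log2 fold changes, with a median of 0.95 and 9 past the threshold when adjusted over the list alone. Among them were HLA-DRA (0.98, SE 0.16), HLA-DMA (0.95, SE 0.16), the invariant chain CD74 (0.99, SE 0.17) and HLA-DPB1 (0.88, SE 0.16), each higher in 6 of 6 specimens. Surface antigens studied on AML stem cells were positive for 16 of 19 genes (median 0.56), 6 of them past the threshold adjusted over the list alone, with CD33 at 1.28 (SE 0.18), LAIR1 at 0.89 (SE 0.16), the hyaluronan receptor CD44 at 1.31 (SE 0.24) and CD200 at 2.24 (SE 0.41). Interferon response genes were positive for 19 of 21 (median 0.44), led by OAS2 (1.20, SE 0.16) and MX1 (0.86, SE 0.15), with 5 past the threshold adjusted over the list alone. Stem and progenitor markers were positive for 14 of 19 (median 0.38), with PROM1 at 1.58 (SE 0.44) and BAALC at 2.31 (SE 0.78), and 0 past the threshold adjusted over the list alone. The 17-gene stemness list was positive for 12 of 17 (median 0.10), with EMP1 at 1.73 (SE 0.41) and FAM30A at 0.93 (SE 0.24), and 2 past the threshold adjusted over the list alone. None of these members passed when adjusted over all genes. As sets they were called higher by camera at the preset correlation (adjusted p = 3.58e-20, 5.63e-10, 5.53e-09, 0.00227 and 4.03e-04). With an estimated correlation each call was lost (adjusted p = 0.141, 0.141, 0.148, 0.276 and 0.258). The estimates were 0.76, 0.07, 0.19, 0.09 and 0.12, against the preset 0.01. Within specimens the MHC class II, surface antigen and stem and progenitor medians were above 0 in 6 of 6. The interferon and 17-gene medians were above 0 in 5 of 6 each. By exact permutation the adjusted p over the lists was 0.161 for each of these lists.

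Erythroid, megakaryocyte, mast cell, NK, T cell and granule markers stood lower in CD99 high bulk blasts, while B cell markers stood higher and the monocyte and dendritic cell lists were not called. All 12 measured erythroid genes were negative (median log2 fold change -4.38), 10 of them past the threshold adjusted over the list alone. GATA1, the erythroid and megakaryocytic transcription factor, averaged 3.20 CPM in CD99 high and 108 CPM in CD99 low (-6.07, SE 0.99), and HBD was at -6.11 (SE 1.56). Megakaryocyte genes were negative for 12 of 13 (median -2.41), with SELP at -2.59 (SE 0.37) and the platelet chemokine PF4 at -3.31 (SE 0.57). Mast cell, basophil and eosinophil genes were negative for 8 of 8 (median -2.31), among them the tryptases TPSAB1 (-2.42, SE 0.45) and TPSB2 (-2.47, SE 0.50), near-identical copies whose reads may be split. NK and cytotoxic genes were negative for 11 of 12 (median -4.75), with GNLY at 2.36 CPM in CD99 high and 240 CPM in CD99 low. T cell genes were negative for 9 of 10 (median -1.61), with CD2 at -2.88 (SE 0.86). Primary granule genes were negative for 12 of 13 (median -1.40), led by neutrophil elastase, ELANE (-3.98, SE 0.50). No member passed when adjusted over all genes. Adjusted over the list alone, 7 megakaryocyte, 5 mast cell, 11 NK, 0 T cell and 1 granule genes passed. All 6 lists were called lower by camera at the preset correlation (adjusted p = 2.14e-18, 9.62e-13, 1.07e-12, 1.21e-12, 1.40e-04 and 2.48e-07 for erythroid, megakaryocyte, mast cell, NK, T cell and granule genes). With an estimated correlation the calls were lost (adjusted p = 0.141, 0.141, 0.141, 0.205, 0.148 and 0.276). The estimates were 0.64, 0.36, 0.49, 0.69, 0.10 and 0.51. Within specimens the erythroid, mast cell and T cell medians were below 0 in 6 of 6. The megakaryocyte, NK and granule medians were above 0 in 1 of 6 each. For granule genes exact permutation p was 0.1875, and 0.3375 adjusted over the lists. No bulk list passed this test (smallest adjusted p = 0.161), where 6 pairs give no unadjusted p under 0.03125. B cell genes were positive for 9 of 13 (median 0.58), with IGHM at 1.56 (SE 0.41), VPREB1 at 1.86 (SE 0.54), JCHAIN at 1.57 (SE 0.48) and DNTT at 3.02 (SE 1.04), each higher in 6 of 6. Adjusted over the list alone, 3 B cell genes passed, and camera called the list higher at the preset correlation (adjusted p = 5.46e-04) and not with an estimated correlation (adjusted p = 0.343). Monocyte genes were positive for 11 of 20 (median 0.16), with ITGAM at 1.59 (SE 0.46, higher in 6 of 6), and dendritic cell genes for 4 of 11 (median -0.41). Neither list was called (adjusted p = 0.0928 and 0.421 at the preset correlation), and the medians of each were above 0 in 3 of 6 specimens. The mitochondrial share of reads averaged 7.74% ± 1.59 in CD99 high and 10.6% ± 1.93 in CD99 low (SD, n = 6 each), and 33144 ± 2975 genes were detected in CD99 low against 31264 ± 1176 in CD99 high (SD, n = 6 each).

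**Figure D2:**
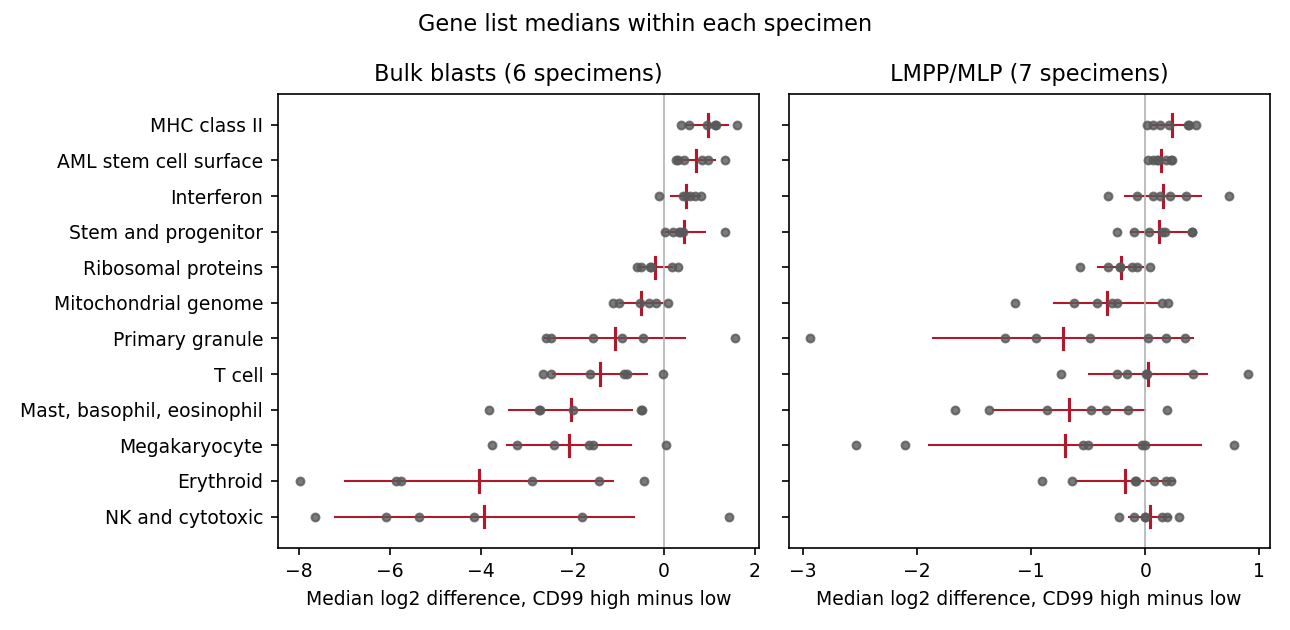
Median log2 difference (CD99 high minus low) of 12 fixed gene lists within each specimen (points), with their mean (vertical bars) and SD (horizontal bars), for bulk blasts (n = 6) and LMPP/MLP cells (n = 7); the panels have different horizontal scales. MHC class II medians are above 0 in 6 of 6 and 7 of 7 specimens, and erythroid medians are below 0 in 6 of 6 bulk specimens.

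In LMPP/MLP cells the genes with the smallest p that were higher in CD99 high cells were TNFSF8, the CD30 ligand (log2 fold change 1.15, SE 0.21), the fructose transporter SLC2A5 (0.73, SE 0.14), CD99, LSP1 (0.49, SE 0.10) and NOTCH3 (1.89, SE 0.41). Those lower were ITGA2B, the platelet integrin CD41 (-1.72, SE 0.36), the mast cell protease CPA3 (-1.21, SE 0.25), POLR1F (-0.64, SE 0.14), VCAN (-1.35, SE 0.29) and TRIM24 (-0.70, SE 0.16). CD34 was at 0.25 (SE 0.24, higher in 5 of 7), CD38 at -0.89 (SE 0.45, higher in 2 of 7) and PTPRC at 0.12 (SE 0.10, higher in 4 of 7). No gene of 17838 was called by edgeR, where the smallest adjusted p was 0.961 and 872 genes had an unadjusted p under 0.05. DESeq2 called 29, limma voom 27, and edgeR 193 without a filter.

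MHC class II genes were positive for 11 of 11 in LMPP/MLP cells (median 0.28), with HLA-DRB1 at 0.28 (SE 0.08) and CIITA, their transcriptional activator, at 0.32 (SE 0.11). AML stem cell surface antigens were positive for 12 of 19 (median 0.24), with CD33 at 0.53 (SE 0.16) and CD82 at 0.40 (SE 0.12), and adhesion genes for 16 of 21 (median 0.12), with ITGB2 at 0.52 (SE 0.13). Mitosis genes were positive for 22 of 24 (median 0.36), with BUB1B at 0.91 (SE 0.30), although their medians were above 0 in 5 of 7 specimens (exact permutation p = 0.406, and 0.736 adjusted over the lists). Ribosomal protein genes were negative for 77 of 78 (median -0.21), with RPL10A at -0.31 (SE 0.08) and RPL13 at -0.25 (SE 0.07). Megakaryocyte genes were negative for 10 of 11 (median -0.91) and mast cell genes for 5 of 6 (median -0.60), with TPSB2 at -1.49 (SE 0.41). The megakaryocyte median was above 0 in 2 of 7 specimens (exact permutation p = 0.219, and 0.547 adjusted over the lists). For mast cell genes it was above 0 in 1 of 7 (0.0469, and 0.205 adjusted). No list in LMPP/MLP passed this test after adjustment (smallest adjusted p = 0.137). Adjusted over the list alone, 1 MHC class II, 1 megakaryocyte and 2 mast cell genes passed, and 0 genes of the surface, adhesion, mitosis and ribosomal lists. In that order, from MHC class II to mast cell genes, camera's adjusted p at the preset correlation was 3.59e-07, 0.0015, 0.00285, 5.00e-04, 1.36e-30, 5.00e-04 and 8.64e-04. With an estimated correlation the calls were lost (adjusted p = 0.336, 0.152, 0.234, 0.574, 0.336, 0.336 and 0.336). The estimates were 0.38, -0.01, 0.02, 0.59, 0.70, 0.36 and 0.29. The mitochondrial share of reads was 4.39% ± 0.73 in CD99 high and 5.37% ± 1.48 in CD99 low (SD, n = 7 each).

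Over 8 specimens, with counts summed per CD99 level, 68 of 23002 genes were called, 48 higher and 20 lower in CD99 high cells. The largest increases among genes of the naming rule were ADAMDEC1, a metalloprotease of the macrophage lineage (log2 fold change 2.19, SE 0.28), TNFSF8 (1.62, SE 0.21), PRSS1 (1.61, SE 0.27), STAB1 (1.60, SE 0.19), TRIM71 (1.42, SE 0.23), the cobalamin carrier TCN2 (1.41, SE 0.22), SULT1B1 (1.28, SE 0.21), GLIPR1 (1.27, SE 0.21), TRBVB (1.26, SE 0.21) and CD99 itself. CD34 rose by 0.98 (SE 0.16, adjusted p = 0.0405, higher in 8 of 8). PTPRC was at 0.34 (SE 0.11, adjusted p = 0.207) and CD38 at -0.998 (SE 0.47, adjusted p = 0.458, higher in 3 of 8). The largest decreases were GATA1 (-5.61, SE 0.77), IL1RL1, the IL-33 receptor of mast cells and type 2 lymphocytes (-4.21, SE 0.66), TC2N (-3.80, SE 0.54), the hematopoietic transcription factor TAL1 (-3.41, SE 0.54), SEPTIN5 (-2.74, SE 0.35), TPSB2 (-2.42, SE 0.39), TPSAB1 (-2.42, SE 0.31), MTDHP3 (-2.40, SE 0.39), TNIK (-2.17, SE 0.33) and C2orf88 (-1.72, SE 0.26). These 20 genes had adjusted p between 0.0179 and 0.0410 by edgeR's quasi-likelihood test and moved one way in all 8 specimens or in 7 of 8. PRSS1 and TRBVB belong to families of similar genes and MTDHP3 is a pseudogene, so their reads are uncertain.

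Of the fixed lists, 3 of 11 MHC class II genes rose over 8 specimens, HLA-DMA (0.58, SE 0.09), HLA-DRB1 (0.61, SE 0.10) and HLA-DMB (0.73, SE 0.12), and 9 of 11 passed adjusted over the list alone. Among the AML stem cell surface antigens CD33 (0.92, SE 0.10) and LAIR1 (0.75, SE 0.10) rose, and among actin cytoskeleton genes the bundling protein LCP1 (0.67, SE 0.06, adjusted p = 0.00977). GATA1 was the called erythroid gene of 12, TPSAB1 and TPSB2 the called mast cell genes of 9, and CEBPE, a transcription factor of granulocytes, the called granule gene of 14 (-2.90, SE 0.50). Adjusted over the list alone, 6 surface, 7 actin, 10 erythroid, 6 mast cell and 3 granule genes passed. Camera at the preset correlation called these lists in the same directions (adjusted p = 4.75e-16 for MHC class II, 1.20e-09 for surface antigens, 6.46e-07 for actin, 1.07e-17 for erythroid, 4.75e-16 for mast cell and 7.05e-10 for granule genes). With an estimated correlation the mast cell list kept its call (adjusted p = 0.0488), and the others lost it (adjusted p = 0.131, 0.0725, 0.246, 0.113 and 0.153). Within specimens the mast cell median was below 0 in 8 of 8 (exact permutation p = 0.00781, the smallest 8 specimens can give, and 0.0578 adjusted over the lists). No list passed that test. Even lists at the smallest possible p had 0.0578 after adjustment, so the miss is limited by the number of specimens and is no evidence against a list. Ribosomal protein genes had a median of 0.00 in the summed counts and -0.21 with the 14 pairs unsummed. The count of 68 changed when single specimens were left out. It was 13 without specimen 1, 31 without specimen 2, 1 without specimen 3 and 48 without specimen 4. It was 30 without specimen 5, 0 without specimen 6, 84 without specimen 7 and 19 without specimen 8. Each fit of this kind also has fewer pairs. It was 0 in edgeR's fit with no specimen block, where 304 genes had an unadjusted p under 0.05. DESeq2 called 891 and limma voom 280. The count was 145 with the 14 pairs unsummed, a fit in which 6 of the 8 specimens gave 2 pairs each and the pairs were taken as independent, where 48 of the 68 were called again and the 64 that were tested kept their direction.

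The CD99 effect was compared between fractions with an interaction term. Since the files of the fractions were made differently, fraction and processing cannot be told apart in this comparison. MHC class II genes had smaller differences in LMPP/MLP than in bulk: the interaction was negative for 11 of 11 genes (median -0.71), and HLA-DRA was at -0.87 (SE 0.16). Among the gate genes the interaction was -0.97 (SE 0.32) for CD99, -2.23 (SE 0.74) for CD34, -0.42 (SE 0.18) for PTPRC, 0.19 (SE 0.78) for CD38 and 0.11 (SE 2.14) for THY1, each with an adjusted p of 1 by edgeR. Within the 6 specimens with both fractions, the difference was larger in bulk in 6 of 6 for PTPRC (0.45 ± 0.19, SD; exact permutation p = 0.03125, the smallest 6 specimens can give) and in 5 of 6 for CD34 (2.40 ± 2.65, SD; exact permutation p = 0.0938), with 0.125 for both adjusted over 4 gate genes. For CD38 it was -0.03 ± 1.93 (SD, n = 6; exact permutation p = 1). The genes with the smallest p among negative interactions were the pseudogene SEPTIN7P8 (-5.02, SE 0.73), HLA-DRA, OAS2 (-0.96, SE 0.18), the pseudogene COX7A2P2 (-4.13, SE 0.70) and NLRP3 (-1.24, SE 0.26), and reads shared with a parent make the pseudogene values uncertain. Among positive interactions they were the erythroid lipid exporter MFSD2B (3.53, SE 0.69), SLC26A2 (0.81, SE 0.20), GNLY (8.10, SE 1.95), TTC27 (1.11, SE 0.29) and CAVIN2 (1.61, SE 0.43). Erythroid genes were positive for 14 of 14 (median 3.92), that is, less negative in LMPP/MLP. Within LMPP/MLP alone, 6 of the 16 listed erythroid genes passed the filter, and 5 of the 12 NK and cytotoxic genes. For a gene near the floor in LMPP/MLP, a positive interaction largely restates its difference in bulk. Camera called the MHC class II and erythroid lists at the preset correlation (adjusted p = 1.47e-19 and 1.20e-10) and neither with an estimated correlation (adjusted p = 0.0739 and 0.135). No gene of 23305 passed edgeR's test of the interaction (smallest adjusted p = 0.374), with 896 at an unadjusted p under 0.05, and DESeq2 called 40 and limma voom 2. These fits took the bulk and LMPP/MLP pairs of specimens 1 to 6 as independent, so they are not paired tests of the difference. Across 17080 genes tested in both fractions the log2 fold changes correlated (Pearson 0.334, Spearman 0.331) and had the same sign in 62.9%. Genes are not independent replicates. Flipping high and low within LMPP/MLP specimens gave absolute correlations of at most 0.295 in the 63 other flips. At an unadjusted p under 0.05, 176 genes were higher in both fractions, against 25.6 from independent lists, and 86 were lower in both, against 14.7.

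LMPP/MLP cells were compared with bulk blasts in specimens 1 to 6. The files of the fractions were made differently, so no difference below, that of CD99 included, can be told apart from one of processing. CD38 fell by 2.88 on the log2 scale (SE 0.78, adjusted p = 0.0165, lower in 6 of 6), CD34 was at 1.37 (SE 0.56, adjusted p = 0.0777, higher in 6 of 6), CD99 rose by 1.83 (SE 0.20, adjusted p = 7.09e-05, higher in 6 of 6) and PTPRC by 0.33 (SE 0.12, adjusted p = 0.0431), a call that median-of-ratios scaling ended (adjusted p = 0.0583). Primary granule genes fell for 11 of 13, among them ELANE (-8.79, SE 1.31), RNASE2 (-3.37, SE 0.59), RNASE3 (-3.51, SE 0.77) and myeloperoxidase, MPO (-3.57, SE 0.80). Monocyte genes fell for 9 of 20, with CD300E at -7.20 (SE 1.31) and CD14 at -7.44 (SE 1.73), whose call limma voom ended (adjusted p = 0.0555). Stem and progenitor markers rose for 9 of 19 and fell for 1, with SPINK2 at 1.57 (SE 0.21), MEIS1 at 1.30 (SE 0.22) and MSI2 at 1.22 (SE 0.23). Camera's adjusted p at the preset correlation was 0.0215, 0.0376 and 0.045 for these lists, and 0.813 for each with an estimated correlation. Adjusted over the list alone, 11 granule and 11 monocyte genes were lower, and 9 stem and progenitor genes were higher and 1 lower. Erythroid genes also fell, for 9 of 12, and 10 were lower when adjusted over the list alone. Camera's adjusted p for them was 0.0332 at the preset correlation and 0.813 with an estimated correlation.

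The largest differences between fractions lay in genes with near-identical copies. All 78 ribosomal protein genes were called higher in LMPP/MLP (median 3.08), with RPS18 at 3.89 (SE 0.12) and RPL12 at 4.69 (SE 0.14), and respiratory chain genes rose for 21 of 24, with UQCRB at 2.28 (SE 0.13). Adjusted over the list alone, 78 and 22 genes were higher. Camera's adjusted p was 8.86e-57 and 5.77e-11, and 0.374 and 0.521 with an estimated correlation. By the naming rule the largest increases included DDT, RPL7, RPL7P1, RPS27P8, RPS3AP26, RPS26P3, RPS3A, RPS3AP6 and RPS3AP20, and the largest decreases were the pseudogenes DDX3P3, PRKAR1AP1, NOL8P1, OSBPL9P2, TRMT1P1, NCOA4P1, CTNNBL1P1, RPS27P27, MYL6P3 and ACTR3P2, for which reads shared with a parent make the values uncertain. Of 3479 processed pseudogenes 2146 were called lower and 381 higher, against 3266 lower and 3271 higher of 13635 protein-coding genes. In all 10825 of 23160 genes were called, 4691 higher and 6134 lower. The files of the fractions were made differently, as their summary rows show, and each fraction had its own kind of file in specimens 1 to 6, so that the batch and the group cannot be told apart in this comparison. The files of specimen 8, with summary rows of the LMPP/MLP kind and conflicting fraction labels, were outside it. Among 11782 protein-coding genes without a named pseudogene and outside the ribosomal list, 5160 were called.

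**Figure D3:**
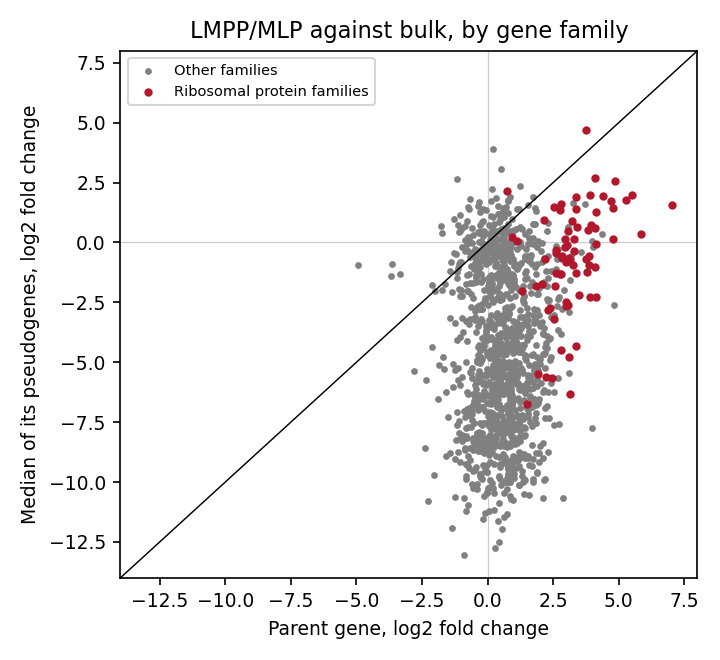
Log2 fold change of LMPP/MLP against bulk for 1267 protein-coding genes (horizontal axis) and the median of the pseudogenes named after each (vertical axis), with ribosomal protein families in red and the line of equality in black. The parent gene has the higher value in 91.7% of families, and the median over 1000 random pairings of parents and pseudogene medians is also 91.7%.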

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

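The tests of reads shared with pseudogenes, of random pairings, of the gate genes, of calls outside pseudogene families, of the share of blasts and of the hemoglobin and tryptase genes were chosen after the results were seen. The thinned counts were also added after. The tests of genes detected, of the unsummed counts and of other splits were set before.

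Some libraries lay far from the rest of their group. Among 73 groups of values examined, 10 such flags arose. About 3.65 would be expected by chance if values were normally spread and groups independent. All 10 lay at the high end and some groups share specimens, so that number is a rough guide only. CD99 reached 2244 CPM in 1 bulk CD99 high library (next 789), 4016 CPM in 1 LMPP/MLP CD99 high library (next 2044) and 3143 CPM in 1 LMPP/MLP CD99 low library (next 1357), all from specimen 4. CD38 reached 612 CPM in 1 bulk CD99 high library (next 149) and 158 CPM in 1 LMPP/MLP CD99 high library (next 44.7). CD34 reached 1281 CPM in 1 bulk CD99 low library (next 410). The ribosomal protein share was 1.60% in 1 bulk CD99 high library (next 1.05%) and 12.8% in 1 LMPP/MLP CD99 low library (next 8.39%). 1 bulk CD99 low library had 38774 genes detected (next 33197). The stem and progenitor median difference was 1.36 in 1 bulk specimen (next 0.43).

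The CD99 effect differed between fractions for 14 lists by camera's test of the interaction at the preset correlation, and for 0 with an estimated correlation. That fit took the bulk and LMPP/MLP pairs of a specimen as independent. Median differences of the effects, LMPP/MLP minus bulk, were -0.71 for MHC class II, -0.62 for S100 and annexin, -0.37 for stem and progenitor, -0.37 for AML stem cell surface, -0.36 for interferon, -0.19 for the 17-gene stemness and -0.16 for actin genes. They were 4.42 for NK, 3.92 for erythroid, 1.59 for megakaryocyte, 0.77 for mast cell, 0.43 for mitosis, 0.26 for cholesterol and 0.23 for DNA replication genes. Within LMPP/MLP alone, 5 of the 12 NK and 6 of the 16 erythroid genes passed the filter, so the NK and erythroid medians largely restate the bulk differences.

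Rows outside the gene counts held reads in one fraction's files and none in the other's: at least 7.51 M reads (M for mega) under the quality limit in each bulk library, and at least 7.44 M without a unique alignment in each LMPP/MLP library.

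Higher ribosomal protein genes and lower processed pseudogenes led LMPP/MLP against bulk. A different handling of reads shared by parents and pseudogenes stays open: the parent had the higher fold change in 91.7% of 1267 families (medians of 0.60 for parents and -4.54 for pseudogenes), but 503 of 1000 random pairings gave a share as high (median 91.7%, range 90.0% to 93.1%), so the share does not bear on a link between a parent and its own pseudogenes. The sorted fractions also differ as gated, with CD34 higher in 6 of 6 specimens and CD38 lower in 6 of 6. For the 5160 genes called outside pseudogene families, processing and fraction cannot be told apart, since they coincide in each of specimens 1 to 6. Specimen 8 was not used to settle it, since its fraction labels conflict and values assign no fraction here: its files have summary rows of the LMPP/MLP kind and ribosomal protein shares of 8.31% and 9.87%, above the highest bulk library (1.60%), while its CD34 (7.31 and 2.19 CPM) lay below the lowest LMPP/MLP library (173 CPM) and its CD38 (276 and 322 CPM) above the highest (171 CPM) and within the bulk range. If these libraries are bulk, as their characteristics say, the ribosomal protein share went with the kind of file and not with the sorted fraction. That reading rests on a single specimen.

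Erythroid, megakaryocyte, mast cell, T cell and NK markers were lower in CD99 high bulk blasts. A difference in genes detected is argued against as the whole cause: with it as a covariate the erythroid median was -4.20, against -4.38 without. For a lower share of blasts in the CD99 low gate, the bound written for the test, a B cell list called in the other direction than the erythroid list, was met (median 0.58, adjusted p = 5.46e-04 at the preset correlation), which by that bound would argue against it. The bound was set aside after the list's genes were seen, and this share is left open. The list was led by IGHM, VPREB1, JCHAIN and DNTT, which blasts may carry. The mature B cell gene MS4A1 was at -2.43 (SE 1.35). It lay near the floor, with an average log2 CPM of -0.24 over the bulk and LMPP/MLP libraries, so its value decides nothing. Erythroid and mast cells in that gate, or blasts with their transcripts, stay open: 4 of the 4 genes HBB, HBA1, HBA2 and TPSAB1 were lower in at least 5 of 6 pairs (HBB at 5.10 CPM in CD99 high and 436 CPM in CD99 low), but they belong to the lists that showed the pattern and only restate it. Which cell types the gate of low CD45 and low side scatter let through was not tested.

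The genes called over 8 specimens come from sums in which bulk reads took 42.4% to 60.5% of the CD99 high counts and 53.4% to 73.0% of the CD99 low counts, more in the low sum in 6 of 6 specimens. This imbalance is argued against as the source of the calls as a set: after thinning every library to one depth before summing, 50 of the 68 were called again and the 65 that were tested kept their direction. With the 14 pairs unsummed 48 of the 68 were called again and the 64 tested kept their direction, but there 6 of the 8 specimens gave 2 pairs each, taken as independent, so that its calls rest on more pairs than specimens. For the ribosomal protein genes it may account for the missing difference, with a median of -0.21 unsummed, -0.16 after thinning and 0.00 in the sums.

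For the 68 genes, 1 of the 60 splits run that part every pair, the real one, gave as many, and the highest other gave 0. These 60 were a sample and not all splits of this kind, so the highest other covers only the splits run. At an unadjusted p under 0.05 it was again 1 of 60, with 2655 genes against at most 2078. For LMPP/MLP against bulk it was 1 of 32, with 10825 genes against 0, and at an unadjusted p 12386 against 5249. For the correlation of the effects it was 1 of 64 flips, with 0.334 against 0.295. Each of these shares is the smallest that its number of splits or flips can give. They were not adjusted for the number of such tests, so they do not exclude chance. At an unadjusted p, chance could not be excluded in bulk alone, where 1871 genes were matched by 3 of 32 splits (highest other 2356), in LMPP/MLP, where 872 were matched by 7 of 64 (highest other 1170), or for the interaction, where 896 were matched by 5 of 32 (highest other 1421). The real counts of 0 past the threshold in these comparisons are matched by any split whatever the data (32 of 32, 64 of 64 and 32 of 32, with 0 as the highest other in each), and say nothing about chance. Splits that part fewer pairs differ: 1 of them called 2337 genes in LMPP/MLP while parting 1 pair. That fit kept the specimen block, so its calls point to 1 specimen whose CD99 high and low libraries differ more than those of the others.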

How the results depend on the processing

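Fits restricted by gene type and the thinned fit were chosen after the data were seen. With edgeR the bulk count of 0 became 164 without a filter, 56 with specimen 8 added and 1 with genes detected as a covariate beside the replicate block, and it ranged from 0 to 3 with 1 specimen left out. DESeq2 gave 751 and limma voom 52. In LMPP/MLP the count of 0 became 193 without a filter, 29 with DESeq2 and 27 with limma voom, and stayed 0 with each specimen left out. The 68 genes over 8 specimens became 234 without a filter, 891 with DESeq2, 280 with limma voom, 145 with the 14 pairs unsummed and 0 with no replicate block, and ranged from 0 to 84 with 1 specimen left out. Each of the 68 that was tested kept its sign under every alternative run. The interaction count of 0 became 8 without a filter, 40 with DESeq2 and 2 with limma voom, and stayed 0 with each specimen left out. The 10825 genes of LMPP/MLP against bulk became 7025 with the stricter filter, 6481 among protein-coding genes and 5160 without named pseudogenes, where fewer genes were tested, and ranged from 9004 to 10495 with 1 specimen left out. Apart from fewer genes or samples, the cause was not tested. DESeq2's counts are to be read beside its 67 false calls of 160 in simulated bulk counts. Those came from a single draw from edgeR's own fit, which may favour edgeR, so they do not give DESeq2's false call rate in the real data.

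The CD99 log2 fold change passed the threshold with DESeq2 at 1.78 in bulk and 0.80 in LMPP/MLP (adjusted p = 9.75e-07 and 0.0046) and with limma voom at 0.57 in LMPP/MLP (adjusted p = 0.0459). It ranged from 1.56 to 1.97 in bulk and from 0.67 to 0.87 in LMPP/MLP with 1 specimen left out. The correlation between fractions moved from 0.334 to 0.502 with the stricter filter. The 21 lists called in bulk and 17 in LMPP/MLP both became 0 with an estimated correlation and ranged from 19 to 23 and from 13 to 21 with 1 specimen left out. With no replicate block 8 lists were called in LMPP/MLP, and 28 named genes lost their call over 8 specimens and 11 in LMPP/MLP against bulk. The block changed no other named gene's call in the comparisons of CD99 or of fractions, and no named gene changed direction under the settings tried on named genes. At the depth and spread of the bulk libraries edgeR recovered 8.96% of simulated 2-fold changes; depth was not varied apart from the other limits.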

Other observations

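The genes NLRP3 and ANXA6 and the levels of the specimen with conflicting labels were picked after their values were seen, and the lists were fixed before. In bulk blasts, S100, annexin and galectin genes were positive for 11 of 13 (median 0.40) and actin cytoskeleton genes for 19 of 21 (median 0.19), while cholesterol and fatty acid synthesis genes were negative for 15 of 16 (median -0.39) and ribosome biogenesis factors for 28 of 29 (median -0.24). Camera's adjusted p at the preset correlation was 2.45e-04, 1.97e-04, 2.00e-04 and 0.00128, and 0.386, 0.47, 0.471 and 0.67 with an estimated correlation. In LMPP/MLP cells cholesterol genes were negative for 12 of 16 (median -0.23), with medians below 0 in 7 of 7 specimens (two-sided exact permutation p = 0.0156, and 0.137 adjusted over the lists), and camera's adjusted p was 0.00119, and 0.152 with an estimated correlation.

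Other genes were called over 8 specimens. NLRP3, the inflammasome sensor, was at 0.94 and ANXA6 at 0.95 on the log2 scale.

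The specimen with conflicting fraction labels had CD34 at 7.31 CPM in its CD99 high and 2.19 CPM in its CD99 low library, below the lowest LMPP/MLP library (173 CPM), and CD38 at 276 and 322 CPM, above the highest LMPP/MLP library (171 CPM). Its ribosomal protein shares, 8.31% and 9.87%, lay within the LMPP/MLP range of 5.19% to 12.8% and above the highest bulk library (1.60%).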
